A study of Mus musculus with 32 samples.

How the data were processed

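RNA was sequenced from 32 laser-captured regions of MMTV-PyMT; R26-CBW; K8-CreERT2 female mice. Per the labels' protocols, tamoxifen (5 mg) at 5 weeks of age switched on a fluorescent colour in keratin 8 cells, sections of 7 µm were fixed, patches of a single colour were cut out at a late tumour stage, normal glands were pooled to reach enough material, and cDNA was made and amplified by a Geo-seq protocol with Smart-seq2 chemistry and Nextera XT libraries. The series states 3 animals, and the labels do not tie a region to an animal.

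The deposited table holds raw counts per gene ID, whole numbers without normalization, for 24454 gene IDs in 32 columns that match the sample titles in stage and number. Per the submitters' processing notes, reads were aligned with STAR to mm10. The counting program, its annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Gene symbols and positions came from the RefSeq annotation of GRCm38.p6, in which 24374 IDs were found and 80 were not. Reads were amplified without molecular identifiers, so counts are not independent molecules.

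Samples were grouped by the stage in the labels (normal 3, hyperplasia 5, adenoma 8, carcinoma 9, metastasis 7), and regions by the stated position for the comparisons of core with border and of lung border with lung centre. Counts were filtered with filterByExpr on stage (19907 genes kept, and 22676 for positions), scaled by TMM and fitted with the edgeR quasi-likelihood model over all libraries with a term per stage, or per stage and position, and tested two-sided at a Benjamini-Hochberg adjusted p of 0.05. The fitted common dispersion was 2.64. CPM values use TMM effective library sizes. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. DESeq2 was run on the same filtered genes with its default independent filtering.

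Lists of marker and pathway genes (25 lists, 475 entries, of which Ltf stands in both the milk and the neutrophil list) were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 25 lists of a comparison. Scores are the mean log2(CPM + 1) over list genes with a mean of 5 CPM or more, and stages were compared by permutation (100000 resamples, or all splits for pairs of stages). Within-stage SDs were set against 10000 random lists of the same size matched on mean expression.

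Comparisons, lists, alternatives and the rule for named genes were chosen before the data were examined. Genes named for a comparison were the 10 of largest change each way among those that passed, with at least 20 CPM in the higher group and 10 counts in 75% of its libraries. Where fewer than 5 passed, the genes of smallest p filled up to 5, given as values only; keeping the level and detection limits for these was decided after values were seen. For each called list the 4 members of smallest p were eligible, and a fixed set of keratin, milk, proliferation and marker genes was always given. Ager, Xist and the genes of the tests in the closing section were named after their values were seen.

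The pipeline was tested on simulated data, written after a first fit to the real data. With no change planted, edgeR made 0 false calls in all 5 stage comparisons, the DESeq2 Wald test made 420, 162, 72, 86 and 442 and limma voom 29, 4, 0, 0 and 7. With 200 genes changed, edgeR recovered 61.5, 75, 81.5, 77.5 and 68% with 2, 9, 22, 23 and 9 false calls, and of genes changed 4-fold it recovered 2 to 30%. The 200 genes had a mean of 20 CPM or more, with 50 each changed 4-, 16-, 64- and 256-fold, so the shares recovered do not cover weaker genes. Genes and libraries were simulated as independent, so the rates may be too favourable for regions that share animals. Alternatives covered scaling, tool, filter, covariates, the samples in the fit, list correlation, score settings, depth and each library left out in turn. The removal of libraries under 25% of the median total count applied to 0 libraries. The alternatives without the gene ID of highest share and without the 3 libraries under 11000 detected genes were chosen after the data were seen. A sequencing batch is not given in the sources used here. Values of 3 genes that fell under these selections are not reported here.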

Results

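RNA of laser-captured patches of mammary tissue was measured in 32 libraries from tumour-bearing female MMTV-PyMT mice, a strain in which a viral oncogene under a mammary promoter drives tumours that pass through graded stages. Patches held cells of a single reporter colour, switched on in cells expressing keratin 8 and passed on to their progeny, except that the labels give normal 28 and 30 as pools. The regions fell into normal gland (3 libraries), hyperplasia (5), adenoma (8), carcinoma (9) and lung metastasis (7). The labels place normal 18 in the tumour core and the other normal libraries in pools of several places. Hyperplasia had 1 region outside the tumour, 1 at its border and 3 in its core, and adenoma had 2, 3 and 3. Carcinoma had 3 at the border and 6 in the core, and metastasis had 4 at the lung border and 3 in the lung centre. The series states 3 animals and does not tie regions to animals, so regions share animals. The p-values over regions treat them as independent and may be too small or too large.

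Total counts per library ranged from 2688611 to 19585351. Between 10258 and 17667 genes had a count. A single gene ID without a symbol took 5.20 to 78.9% of the counts of a library, with a median of 24.7%. Hyperplasia 22, metastasis 42 and adenoma 51 had the fewest detected genes, with 10258, 10383 and 10769. Normal libraries had 16823 ± 679 detected genes (SD, n = 3), against 14014 ± 2464 in hyperplasia (n = 5), 13728 ± 1743 in adenoma (n = 8), 15834 ± 1336 in carcinoma (n = 9) and 14660 ± 2598 in metastasis (n = 7). Spearman's rho between pairs of libraries, taken across genes, which are not independent, had a median of 0.707 over 98 pairs of the same stage and 0.688 over 398 pairs of different stages. Regions of one stage were thus little more alike than regions of different stages. Intervals and floors given here cover counting error only.

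Epithelial identity genes were measured in every stage. Krt8, the keratin of the cells in which the reporter was switched on, stood at 318 ± 104 CPM in normal gland, 670 ± 234 in hyperplasia, 856 ± 285 in adenoma, 746 ± 326 in carcinoma and 592 ± 108 in metastasis (mean ± SD, n = 3, 5, 8, 9 and 7). Its partner Krt18 stood at 298 ± 135, 518 ± 191, 572 ± 171, 654 ± 271 and 511 ± 227 CPM in the same order. Cdh1, the epithelial adhesion protein E-cadherin, lay between a mean of 127 CPM in hyperplasia and 185 CPM in adenoma. Krt14, a keratin of basal cells, had means of 65.7, 69.2, 21.9, 20.7 and 31.7 CPM from normal gland to metastasis, and Vim, a filament protein of mesenchymal cells, had means of 98.2, 35.6, 13.4, 48.5 and 27.9 CPM. Esr1, the oestrogen receptor, had means of 28.9, 61.1, 56.4, 28.6 and 55.9 CPM. Csn3, a milk casein, was abundant throughout, with means from 3086 CPM in normal gland to 8970 CPM in hyperplasia. The casein Csn2 reached 7852 CPM in hyperplasia 46 and 3158 CPM in a metastasis and stayed at or below 41.1 CPM in every normal, adenoma and carcinoma library. Wap, a whey protein, had means of 43.1, 219, 64.8, 116 and 132 CPM.

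Proliferation varied between regions of the same stage, the subject of the series title. The proliferation score, the mean log2(CPM + 1) over 95 genes of DNA synthesis and of mitosis, was 3.53 ± 0.07 in normal gland (SD, n = 3), 4.09 ± 1.39 in hyperplasia (n = 5), 4.30 ± 0.92 in adenoma (n = 8), 4.27 ± 0.40 in carcinoma (n = 9) and 4.33 ± 0.71 in metastasis (n = 7). Scores ran from 1.68 to 5.03 in hyperplasia, from 2.23 to 5.09 in adenoma, from 3.55 to 4.91 in carcinoma and from 3.31 to 5.20 in metastasis. The lowest scores, in hyperplasia 22 and adenoma 51, came from libraries with under 11000 detected genes and made most of the spread of their stages. Without hyperplasia 22 the SD of hyperplasia was 0.40, and without adenoma 51 that of adenoma was 0.43. Mki67, a marker of cycling cells, had means of 61.3 ± 68.3, 193 ± 93.8, 155 ± 74.2, 120 ± 62.3 and 117 ± 72.8 CPM from normal gland to metastasis. Top2a, which untangles DNA for mitosis, had means of 57.4, 108, 113, 98.5 and 156 CPM, Ccnb1, the mitotic cyclin, 23.4, 34, 44.3, 25.6 and 40.7 CPM, and Mcm2, part of the replicative helicase, 14.4, 35, 33.4, 40 and 39.5 CPM.

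The score did not pass a test of its level between stages (permutation p = 0.652, two-sided over 5 stages) or of its mean absolute deviation from the stage median (permutation p = 0.463). Those deviations were 0.04 in normal gland, 0.81 in hyperplasia, 0.58 in adenoma, 0.30 in carcinoma and 0.56 in metastasis, so a difference in spread between stages was not shown. Of the 5 pairs of stages, carcinoma stood 0.74 above normal gland (exact permutation p = 0.0227 over 220 splits, adjusted p = 0.114), and the others had exact permutation p from 0.571 to 0.931. Within stages, the pooled SD of the score was 0.81, against a median of 0.31 for random lists of genes of like expression, a spread that none of 10000 lists reached (permutation p = 0.0001, the smallest they can give, adjusted p = 0.00024). Random lists were matched on expression and not on co-regulation. Any list of genes that move together tends to exceed them, so the test shows joint variation of the list's genes. The pooled SD was 0.64 without hyperplasia 22 and 0.70 without adenoma 51. Without the 3 libraries with fewer than 11000 detected genes it was 0.48, against 0.19 for random lists (permutation p = 0.0001, the smallest they can give, adjusted p = 0.000267). Proliferation was not the most variable group: it ranked 4 of 24 by the ratio to random lists, after the red blood cell, interferon response and fibroblast lists, and 6 of 24 without the 3 libraries. The 24 include its S phase and G2 and M phase parts, and the ratio depends on list length, since longer random lists average to smaller SDs. By pooled SD alone, the macrophage, basal, immediate early, milk, adipocyte and epithelial-mesenchymal transition lists also exceeded the score. Without the 3 libraries, an alternative chosen after the data were seen, the level between stages gave permutation p = 0.0447. The p-values over regions do not account for shared animals, and those against random lists resample genes and not regions.

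**Figure D1:**
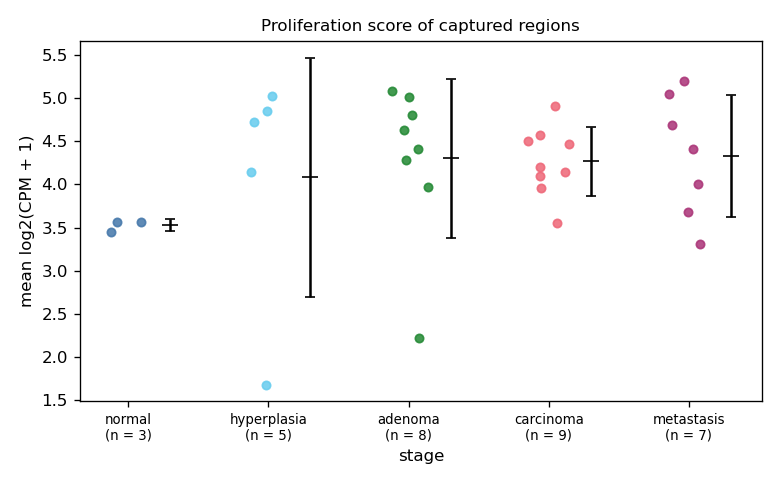
Proliferation score of each library, the mean log2(CPM + 1) over 95 S phase and G2 and M phase genes (vertical axis), by stage (horizontal axis), with the mean and SD of each stage. Scores of hyperplasia ran from 1.68 to 5.03 and those of the 3 normal libraries from 3.45 to 3.57.

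The step from normal gland to hyperplasia, the earliest of the tumour stages, showed lower levels of connective tissue and fat genes. Camera also called lists of cell division, protein synthesis and respiration higher, none of which held with an estimated correlation. Of the fibroblast and matrix list, 14 of 16 genes were lower in hyperplasia and the list fell (median log2 -2.17, camera adjusted p = 1.70e-10). Col3a1, a fibrillar collagen chain, stood at 57.7 ± 38.4 CPM in hyperplasia and 394 ± 298 CPM in normal gland (SD, n = 5 and 3), and Col1a1 at 87.1 ± 92.8 and 485 ± 326 CPM. Dpt, a matrix protein, had no count in hyperplasia and 10.4 ± 7.81 CPM in normal gland, at least 157-fold lower against a floor of 3 counts over the group. All 16 measured genes of the epithelial-mesenchymal transition list were lower and the list fell (median log2 -2.30, adjusted p = 5.03e-08). Zeb1, a transcription factor of that programme, stood at 0.220 ± 0.491 against 33.1 ± 31.6 CPM and the matrix protein Fn1 at 12.4 ± 6.17 against 72.0 ± 71.8 CPM. The mean score of this list was 5.63 in normal gland and 3.25 in hyperplasia, beside 6.25 and 3.83 for the fibroblast list. A change in epithelial cells thus cannot be told apart from less connective tissue in the captured regions. The adipocyte list fell with 9 of 11 genes lower (median log2 -2.06, adjusted p = 1.98e-06). Cfd, a complement factor secreted by fat cells, stood at 1.89 ± 4.21 against 223 ± 197 CPM. Normal means without normal 18 were 239 CPM for Col3a1, 320 for Col1a1, 30.8 for Fn1 and 119 for Cfd, that of Dpt without normal 28 was 5.96 and that of Zeb1 without normal 30 was 17.5.

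Markers of immune and basal cells moved the same way between these stages. The basal and myoepithelial list fell with 11 of 12 genes lower (median log2 -1.13, adjusted p = 0.000199, 0.0847 as the adjusted p with an estimated correlation). Mylk, the kinase of contracting cells, stood at 4.96 ± 6.75 against 42.0 ± 18.9 CPM. The macrophage and antigen presentation list fell with 15 of 17 genes lower (median log2 -1.64, adjusted p = 0.0002, adjusted p = 0.130 with an estimated correlation). The complement gene C1qa stood at 18.6 ± 23.8 against 114 ± 82.3 CPM. The T, NK and B cell list fell with 11 of 14 genes lower (median log2 -4.83, or -4.01 with genes absent from a group at their bound, adjusted p = 0.00487, adjusted p = 0.195 with an estimated correlation). Jchain, of antibody-secreting cells, stood at 4.87 ± 9.45 against 379 ± 456 CPM, or 122 CPM without normal 18. The interferon response list fell with 16 of 25 genes lower (median log2 -0.47, adjusted p = 0.0184, adjusted p = 0.520 with an estimated correlation). Isg15 stood at 0.227 ± 0.208 against 8.38 ± 4.59 CPM.

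Lists of cell division, protein synthesis, metabolism, stress and epithelial identity rose in hyperplasia. The G2 and M phase list rose with 41 of 54 genes higher (median log2 0.90, adjusted p = 7.39e-07, adjusted p = 0.206 with an estimated correlation). Ube2c, which marks mitotic proteins for destruction, stood at 161 ± 84.7 against 22.0 ± 16.1 CPM and the survival and spindle protein Birc5 at 200 ± 146 against 18.6 ± 0.322 CPM. The S phase list rose with 31 of 42 genes higher (median log2 0.79, adjusted p = 0.0443, adjusted p = 0.520 with an estimated correlation). Rrm2, which makes DNA precursors, stood at 88.6 ± 88.2 against 9.43 ± 11.6 CPM, with a hyperplasia mean of 54 CPM without hyperplasia 46. Cell cycle inhibitors also rose, with 11 of 18 genes higher (median log2 0.53, adjusted p = 0.0273, adjusted p = 0.160 with an estimated correlation). All 38 ribosomal protein genes were higher and the list rose (median log2 0.49, adjusted p = 1.70e-10, adjusted p = 0.193 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose with 18 of 20 higher (median log2 0.92, adjusted p = 6.77e-06, adjusted p = 0.130 with an estimated correlation). The epithelial junction and luminal keratin list rose with 12 of 16 genes higher (median log2 0.88, adjusted p = 0.000248, adjusted p = 0.0847 with an estimated correlation). Fatty acid synthesis rose with 9 of 11 (median log2 0.78, adjusted p = 0.00173, adjusted p = 0.0831 with an estimated correlation), and the desaturase Scd2 stood at 383 ± 254 against 83.9 ± 71.9 CPM. The unfolded protein and amino acid stress list rose with 13 of 16 genes higher (median log2 0.41, adjusted p = 0.00526, adjusted p = 0.196 with an estimated correlation). The stress regulator Atf4 stood at 347 ± 252 against 74.6 ± 10.7 CPM. Immediate early and heat shock genes rose with 16 of 17 higher (median log2 1.82, adjusted p = 0.00944, adjusted p = 0.272 with an estimated correlation), Fos standing at 473 ± 956 against 28.5 ± 2.91 CPM, with 2183 CPM in hyperplasia 22 and a mean of 45.5 CPM without it. With DESeq2 size factors, where the median of all genes was -0.35, the medians of these lists were 0.44 for G2 and M phase (33 of 54 genes higher), 0.32 for S phase (28 of 42), 0.09 for inhibitors (10 of 18), 0.09 for ribosomal proteins (27 of 38) and 0.50 for oxidative phosphorylation (15 of 20). They were 0.36 for epithelial junctions (11 of 16), 0.35 for fatty acid synthesis (8 of 11), 0.16 for unfolded protein stress (9 of 16) and 1.61 for immediate early genes (14 of 17).

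No single gene passed between hyperplasia and normal gland by edgeR, where 2472 of 19907 genes had an unadjusted p under 0.05, against a median of 1841 in other splits of the same libraries. The DESeq2 Wald test called 489 genes, 138 higher and 351 lower, and limma voom with sample weights called 105, all lower. The genes of smallest p, given as values only, included Ttpa, a vitamin E carrier (120.2 ± 91.4 against 7.22 ± 2.49 CPM), Cd24a, a surface protein of epithelial cells (611 ± 283 against 141 ± 39.8 CPM), Gatc and Plet1. Lower in hyperplasia were the Schlafen gene Slfn9 (0.515 ± 0.445 against 68.6 ± 102 CPM), Slfn10-ps, Zfp872, Olfr787 and Mif4gd. Normal means with and without normal 28 were 68.6 and 9.58 CPM for Slfn9, 91.3 and 22.0 for Slfn10-ps, 47.4 and 8.88 for Zfp872, 44.5 and 5.47 for Olfr787 and 38.4 and 24.7 for Mif4gd. The hyperplasia mean of Gatc was 152 CPM with hyperplasia 22 and 94.0 without. Of the 16 lists called by camera, 3 held with an estimated correlation: the epithelial-mesenchymal transition, fibroblast and adipocyte lists, each with adjusted p = 0.0492. Adjusted over the list alone, 6 milk genes, 2 G2 and M phase genes and 1 gene each of the lung epithelium, unfolded protein and fatty acid lists were higher, and 2 adipocyte genes and 1 hormone-sensing gene were lower. The milk list itself was not called. Its score was 9.19 in hyperplasia 46 and 5.42 to 6.48 in the other hyperplasia libraries, against a mean of 5.83 in normal gland. Regions of shared animals were treated as independent. Leaving out a library ended several of these calls. The S phase call was lost without normal 18 (adjusted p = 0.148), 28 (0.0767) or 30 (0.0639) and without hyperplasia 21 (0.248), 44 (0.0580), 33 (0.121) or 46 (0.175). The inhibitor call was lost without normal 28 (0.0837) or 30 (0.0993), hyperplasia 22 (0.0758) or 46 (0.0712), with the number of detected genes as a covariate (0.0827) and without the 3 libraries of fewest genes (0.0774). The immediate early call was lost without hyperplasia 22 (0.509), with the covariate (0.144) and without the 3 libraries (0.557). The interferon call was lost without normal 18 (0.178), hyperplasia 22 (0.183) or 33 (0.160) and without the 3 libraries (0.139). The macrophage and T, NK and B cell calls were lost without normal 18 (0.566 and 0.0908), and the unfolded protein call without normal 30 (0.0520) and with the covariate (0.0829).

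Between hyperplasia and adenoma, the next step of growth, camera called the connective tissue list lower. The fibroblast and matrix list fell with 13 of 16 genes lower (median log2 -0.23, camera adjusted p = 0.0156, adjusted p = 0.831 with an estimated correlation). Postn, a matrix protein of remodelled tissue, stood at 22.8 ± 21.4 CPM in adenoma and 102 ± 92.3 CPM in hyperplasia (SD, n = 8 and 5), and Col6a1 at 22.1 ± 31.0 against 105 ± 170 CPM. Fbln1 had no count in adenoma and 4.16 ± 5.36 CPM in hyperplasia, at least 115-fold lower, whereas Dpt had no count in hyperplasia and 5.69 ± 12.5 CPM in adenoma, at least 85.6-fold higher. Hyperplasia means without hyperplasia 22 were 65.2 CPM for Postn and 30.0 for Col6a1, that of Fbln1 without hyperplasia 44 was 2.42, and the adenoma mean of Dpt without adenoma 36 was 1.37. Adjusted over the list alone, 1 fibroblast gene was higher and 1 lower, and over all lists 3 genes were higher and 10 lower. The other 24 lists were not called.

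No gene passed between adenoma and hyperplasia by edgeR, where 2947 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.0963. The DESeq2 Wald test called 609 genes, 371 higher and 238 lower, and limma voom called 2. The genes of smallest p, as values only, were Crb1, an epithelial polarity gene (0.0265 ± 0.0749 CPM in adenoma against 53.9 ± 78.7 CPM in hyperplasia), Stc1 (0.538 ± 0.695 against 118 ± 217 CPM), Vkorc1, Cebpd and Rfx2, lower in adenoma. Higher in adenoma were Sms, spermine synthase (139 ± 320 against 7.90 ± 6.67 CPM), Mob1b, Zfp296, Zfp358 and Mpnd. Single libraries weighed on these means. Adenoma means with and without adenoma 51 were 139 and 25.7 CPM for Sms, 118 and 7.03 for Mob1b, 57 and 5.52 for Zfp296, 74.8 and 20.6 for Zfp358 and 159 and 98.2 for Mpnd. Hyperplasia means with and without hyperplasia 22 were 118 and 21.3 CPM for Stc1, 264 and 132 for Vkorc1 and 207 and 39.4 for Cebpd. They were 67.3 and 12.1 for Rfx2 with and without hyperplasia 46, and 53.9 and 19.5 for Crb1 with and without hyperplasia 33. Regions share animals here too, and no list call held with an estimated correlation. Other splits of the same libraries called a median of 5 lists, against 1 here. The fibroblast call was lost without hyperplasia 44 (adjusted p = 0.192) or 22 (0.245), without adenoma 24 (0.0511), 34 (0.0745) or 47 (0.0510) and without the 3 libraries of fewest genes (0.570). The number of lists called was 3 without hyperplasia 21, 0 without hyperplasia 44, 2 without hyperplasia 33, 6 without hyperplasia 46, 0 without adenoma 24, 34 or 47, 4 without adenoma 25 or 36 and 5 without adenoma 51.

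From adenoma to carcinoma, the step to malignancy, camera called the interferon and connective tissue lists higher and the G2 and M phase list lower, none of which held with an estimated correlation. The interferon response list rose with 19 of 25 genes higher (median log2 0.99, camera adjusted p = 3.54e-09, adjusted p = 0.348 with an estimated correlation). The antiviral gene Ifit2 stood at 17.2 ± 29.8 CPM in carcinoma and 1.10 ± 1.72 CPM in adenoma (SD, n = 9 and 8) and Psmb8, a subunit of the immunoproteasome, at 475 ± 412 against 198 ± 358 CPM. The fibroblast and matrix list rose with 13 of 16 genes higher (median log2 1.04, adjusted p = 0.0163, adjusted p = 0.855 with an estimated correlation). Col1a1 stood at 136 ± 210 against 41.7 ± 53.4 CPM and Fbln1 at 6.17 ± 13.2 CPM against no count in adenoma, at least 171-fold higher. The G2 and M phase list fell with 46 of 54 genes lower (median log2 -0.40, adjusted p = 0.00552, adjusted p = 0.855 with an estimated correlation). Ube2c stood at 113 ± 56.1 against 244 ± 121 CPM and Anln, a scaffold of the dividing cell's contractile ring, at 8.14 ± 6.42 against 45.1 ± 41.2 CPM. With tumour core regions alone the log2 of Anln was 0.10 in place of -2.47. Carcinoma means without carcinoma 55 were 69.5 CPM for Col1a1 and 1.82 for Fbln1, and that of Ifit2 without carcinoma 54 was 8.91. The S phase list was not called (adjusted p = 0.460).

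No gene passed between carcinoma and adenoma by edgeR, where 2502 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.141. The DESeq2 Wald test called 265 genes, 191 higher and 74 lower, and limma voom called 7, 5 higher and 2 lower. Genes of small p, as values only, included Mmp14, a protease that cuts matrix (72.5 ± 37.5 against 12.0 ± 10.5 CPM), the ubiquitin ligase Wwp2 (123 ± 120 against 27.5 ± 20.3 CPM), Ccdc157 and Coro2a, higher in carcinoma. Lower were the splicing helicase Snrnp200 (60.6 ± 21 against 213 ± 200 CPM), Cep19, Mob1b, Abca8a and Hnrnph2. Adenoma means with and without adenoma 51 were 213 and 149 CPM for Snrnp200, 100 and 37.7 for Cep19 and 118 and 7.03 for Mob1b. With and without adenoma 36 they were 31.5 and 7.05 for Abca8a and 92.6 and 17.4 for Hnrnph2. The carcinoma mean of Coro2a was 33.8 CPM with carcinoma 39 and 15.7 without. With the number of detected genes as a covariate, edgeR called 168 genes, 11 higher and 157 lower, and without carcinoma 37 it called 1. Adjusted over the list alone, 3 T, NK and B cell genes and 1 gene each of the epithelial-mesenchymal transition, fibroblast, adipocyte and lung epithelium lists were higher, and 2 adipocyte genes and 1 neutrophil gene were lower. None of the 3 lists held with an estimated correlation, and regions share animals. Other splits of the same libraries called a median of 6 lists. The G2 and M phase call was lost without adenoma 34 (adjusted p = 0.142) or carcinoma 53 (0.0680). The fibroblast call was lost without adenoma 24 (0.0684), 34 (0.0601), 47 (0.0961) or 51 (0.0514), carcinoma 07 (0.0598), 54 (0.0895) or 55 (0.348) and without the 3 libraries of fewest genes (0.0603). The number of lists called was 5 without adenoma 51 or 36 and 7 without carcinoma 37.

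Lung metastases differed from carcinomas first in genes of the surfactant that coats the air spaces of the lung. Sftpc (gene ID 20389, chromosome 14, 70520941 to 70524081 on GRCm38), which encodes surfactant protein C of alveolar type 2 cells, stood at 1544 ± 1467 CPM in metastasis and 0.0706 ± 0.212 CPM in carcinoma (SD, n = 7 and 9). It rose by 15.03 ± 0.99 in log2 (SE, edgeR adjusted p = 3.52e-14). Its carcinoma counts summed to 3, and the pooled ratio was 61680 with a 95% counting interval of 21110 to 299100. Sftpb (gene ID 20388, chromosome 6, 72304610 to 72314373) stood at 129 ± 84.8 against 0.258 ± 0.515 CPM and rose by 8.88 ± 1.23 (adjusted p = 7.12e-05). Sftpa1 (gene ID 20387, chromosome 14, 41131788 to 41136373) stood at 143 ± 129 against 0.142 ± 0.347 CPM and rose by 10.25 ± 1.44 (adjusted p = 0.000203). These genes were detected in 7 of 7 metastases, with the lowest library at 246 CPM for Sftpc, 39.6 CPM for Sftpb and 11.7 CPM for Sftpa1.

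Other cell type lists rose in the metastases. The lung epithelium list rose with 12 of 16 genes higher (median log2 2.02, camera adjusted p = 2.19e-23), and with the 3 called genes left out it kept camera adjusted p = 7.43e-09. Scgb1a1, the secretory protein of club cells, stood at 12.6 ± 16.5 against 0.0372 ± 0.111 CPM, and Ager, of alveolar type 1 cells, at 29.4 ± 27.3 against 2.06 ± 2.85 CPM. Of the 16 genes, 3 had a median of 5 CPM or more in the libraries of the other stages. All 12 neutrophil genes were higher and the list rose (median log2 4.08, adjusted p = 3.57e-19). S100a9 stood at 115 ± 103 against 1.13 ± 2.24 CPM, S100a8 at 236 ± 210 against 17.4 ± 17.0 CPM, and Retnlg and Camp had no count in carcinoma and were at least 457-fold and at least 170-fold higher. The endothelial list rose with 11 of 13 genes higher (median log2 1.5, adjusted p = 1.15e-05). Cdh5, the adhesion protein of vessel lining, stood at 20.9 ± 18 against 3.06 ± 3.63 CPM. The milk and secretory list rose with 14 of 18 genes higher (median log2 0.62, adjusted p = 2.54e-07). Csn2 stood at 675 ± 1240 against 13.4 ± 15.7 CPM, with 3158 and 1565 CPM in metastases 42 and 58, at most 3.29 CPM in the other 5 and a mean of 262 CPM without metastasis 42, and Ltf, lactoferrin, at 1478 ± 793 against 443 ± 602 CPM. Ltf is made by both gland and neutrophils and was the only gene held by more than 1 list. Without it the neutrophil and milk lists had camera adjusted p = 1e-15 and adjusted p = 1.62e-05. The red blood cell list rose with 7 of 8 genes higher (median log2 3.54, adjusted p = 6.69e-06, adjusted p = 0.174 with an estimated correlation). The globin gene Hba-a1 stood at 1475 ± 2025 against 105 ± 135 CPM, and its near-identical copy Hba-a2 carried nearly the same counts, so the globin members are not independent. Metastasis means were 757 CPM for Hba-a1 without metastasis 56, 6.57 for Scgb1a1 without metastasis 58, 2.26 for Retnlg without metastasis 02 and 2.94 for Camp without metastasis 42.

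Camera called the connective tissue and hypoxia lists lower in the metastases, neither of which held with an estimated correlation. The fibroblast and matrix list fell with 15 of 16 genes lower (median log2 -2.09, adjusted p = 2.54e-07, adjusted p = 0.105 with an estimated correlation). Col1a1 stood at 20.5 ± 19.2 against 136 ± 210 CPM (69.5 in carcinoma without carcinoma 55) and Dcn, decorin, at 0.822 ± 1.01 against 15.5 ± 17.3 CPM. The hypoxia and glycolysis list fell with 18 of 23 genes lower (median log2 -0.51, adjusted p = 0.00653, adjusted p = 0.346 with an estimated correlation). The glycolytic enzyme Aldoa stood at 621 ± 140 against 1214 ± 1120 CPM. The basal and myoepithelial list rose with 10 of 12 genes higher (median log2 0.90, adjusted p = 0.0247), and the G2 and M phase list with 36 of 54 (median log2 0.47, adjusted p = 0.0163). The immediate early and heat shock list rose with 15 of 17 (median log2 0.41, adjusted p = 0.00653) and the oxidative phosphorylation list with 17 of 20 (median log2 0.22, adjusted p = 0.00469). With an estimated correlation these 4 lists had adjusted p = 0.346, 0.691, 0.346 and 0.346. The interferon response list was called lower by camera (adjusted p = 0.0209, adjusted p = 0.691 with an estimated correlation) although its median and mean log2 were 0.24 and 0.46, so test and average differed in sign.

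Between metastasis and carcinoma edgeR called 3 genes, all higher, where 2164 had an unadjusted p under 0.05, and the same 3 genes were among those called in every alternative tried. The DESeq2 Wald test called 186 genes, 85 higher and 101 lower, limma voom called 19, 16 higher and 3 lower, and edgeR without a filter called 5. Further genes of small p, as values only, were Chp1, higher in metastasis (means of 154 and 39.4 CPM with and without metastasis 42, against 20.0 in carcinoma), and Ercc2, a DNA repair helicase (64 ± 39.5 against 215 ± 107 CPM), Klc3, Pmepa1, Ddah1 and the potassium channel gene Kcnn4, lower. Of 12 lists, 4 held with an estimated correlation: lung epithelium (adjusted p = 3.88e-07), neutrophil (3.62e-05), milk (0.000422) and endothelial (0.00550). Adjusted over the list alone, 7 neutrophil, 6 lung epithelium, 6 red blood cell, 2 milk and 1 adipocyte genes were higher, and 5 fibroblast, 2 adipocyte and 1 lung epithelium genes were lower. These p-values do not account for shared animals and may be too small or too large. The G2 and M phase call was lost without carcinoma 53 (adjusted p = 0.117) or 39 (0.0657), metastasis 57 (0.397), 58 (0.0592) or 27 (0.0792) and with the number of detected genes as a covariate (0.0715). The basal call was lost without carcinoma 37 (0.0539) or 08 (0.104) and metastasis 40 (0.0525), 58 (0.0542) or 27 (0.0686). The hypoxia call was lost without carcinoma 37 (0.0715) or metastasis 40 (0.0701). The immediate early call was lost without metastasis 02 (0.0962) and with the covariate (0.181), which also ended the oxidative phosphorylation call (0.0510). The interferon call was lost without carcinoma 06 (0.139), 54 (0.179) or 08 (0.161) and metastasis 02 (0.0962), 40 (0.0637), 57 (0.0956) or 27 (0.444).

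**Figure D2:**
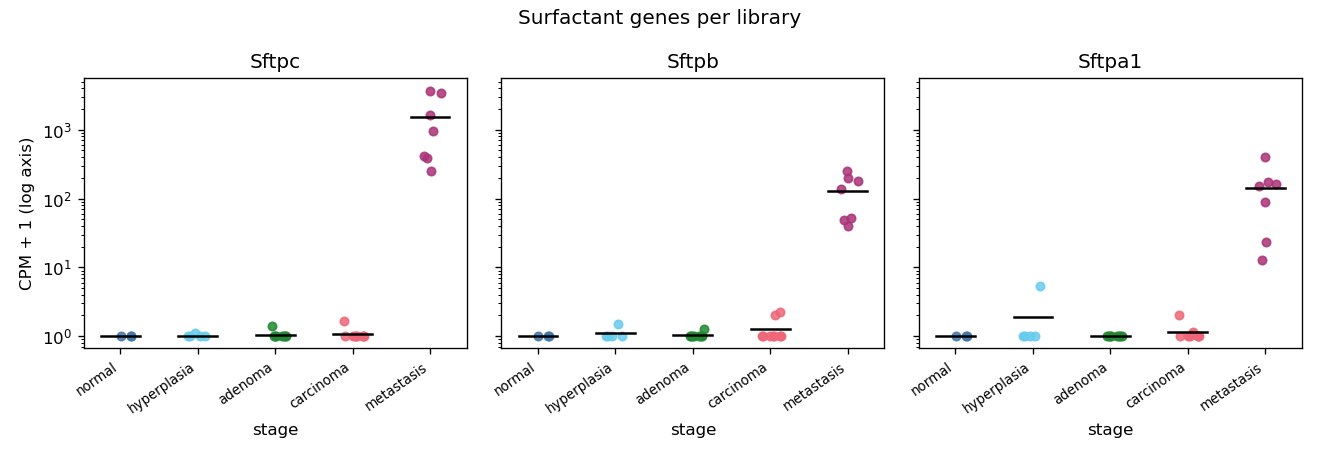
Levels of Sftpc, Sftpb and Sftpa1 (CPM + 1, log axis) in each library by stage, with a line at the mean. The 7 metastases sit at or above 246 CPM for Sftpc, and the other 25 libraries at or below 0.636 CPM.

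Carcinoma was set against normal gland to span the whole course in the gland. Cfd (gene ID 11537, chromosome 10, 79890853 to 79892655), the complement factor secreted by fat cells, fell by 10.77 ± 1.70 in log2 (SE, edgeR adjusted p = 0.00454). It went from 223 ± 197 CPM in normal gland (SD, n = 3) to 0.100 ± 0.301 CPM in carcinoma (n = 9), and carcinoma 07 alone had counts, at 0.904 CPM. The adipocyte list fell with 8 of 11 genes lower (median log2 -4.00, camera adjusted p = 1.56e-13). Car3 stood at 0.0932 ± 0.280 against 84.6 ± 84.2 CPM and the fatty acid carrier Fabp4 at 4.40 ± 4.10 against 99.6 ± 92.4 CPM. The fibroblast and matrix list fell with 16 of 16 genes lower (median log2 -1.77, adjusted p = 5.63e-16). Col3a1 stood at 68.4 ± 113 against 394 ± 298 CPM. The epithelial-mesenchymal transition list fell with 16 of 16 genes lower (median log2 -1.73, adjusted p = 2.64e-08). The matrix protease Mmp2 stood at 16.6 ± 19.5 against 169 ± 93.9 CPM. Here too a change in epithelial cells cannot be told apart from less connective tissue in the captured regions. The macrophage list fell with 17 of 17 genes lower (median log2 -1.75, adjusted p = 4.89e-08). The lysozyme Lyz2 stood at 36.6 ± 50.8 against 614 ± 976 CPM, or 50.1 CPM without normal 18, without which the list was not called. The basal and myoepithelial list fell with 11 of 12 genes lower (median log2 -1.32, adjusted p = 1.80e-05). Krt14 stood at 20.7 ± 24.6 against 65.7 ± 45.8 CPM, or 40.1 CPM without normal 30. Without normal 18 the normal means were 46.5 CPM for Fabp4 and 239 for Col3a1. Endothelial genes fell with 12 of 13 lower (median log2 -1.35, adjusted p = 0.00419), T, NK and B cell genes with 11 of 14 (median log2 -1.58, adjusted p = 0.00566) and neutrophil genes with 8 of 12 (median log2 -0.98, adjusted p = 0.00566). With an estimated correlation their adjusted p = 0.0727, 0.187 and 0.166.

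Camera called lists of cell division, metabolism, stress, epithelial junctions and red blood cells higher in carcinoma than in normal gland, none of which held with an estimated correlation. The G2 and M phase list rose with 41 of 54 genes higher (median log2 0.95, adjusted p = 4.89e-08, adjusted p = 0.175 with an estimated correlation). Birc5 stood at 130 ± 90.8 against 18.6 ± 0.322 CPM. The S phase list rose with 31 of 42 genes higher (median log2 0.48, or -0.09 with 20 of 42 higher by DESeq2 size factors, adjusted p = 0.00105, adjusted p = 0.352 with an estimated correlation). Uhrf1, which copies DNA methylation, stood at 61.9 ± 33.1 against 15.8 ± 10.7 CPM. Ribosomal protein genes rose with 37 of 38 higher (median log2 0.62, adjusted p = 2.85e-11, adjusted p = 0.166 with an estimated correlation). Oxidative phosphorylation genes rose with 17 of 20 (median log2 0.66, adjusted p = 9.76e-05, adjusted p = 0.166 with an estimated correlation). The hypoxia and glycolysis list rose with 16 of 23 genes higher (median log2 1, adjusted p = 0.00371, adjusted p = 0.175 with an estimated correlation). Egln3, an oxygen sensor, stood at 89.4 ± 88.7 against 8.38 ± 6.08 CPM. The epithelial junction and luminal keratin list rose with 14 of 16 genes higher (median log2 0.83, adjusted p = 9.98e-05, adjusted p = 0.0529 with an estimated correlation). The tight junction gene Cldn3 stood at 525 ± 245 against 211 ± 41.9 CPM. Sterol synthesis rose with 13 of 16 genes higher (median log2 0.74, adjusted p = 0.00299), fatty acid synthesis with 9 of 11 (median log2 0.72, adjusted p = 0.00277) and the unfolded protein and amino acid stress list with 16 of 16 (median log2 0.72, adjusted p = 0.000802). With an estimated correlation their adjusted p = 0.214, 0.0656 and 0.150. The red blood cell list rose with 8 of 8 genes higher (median log2 1.95, adjusted p = 0.0439, adjusted p = 0.442 with an estimated correlation). With DESeq2 size factors, where the median of all genes was -0.31, the other medians were 0.42 for G2 and M phase (33 of 54 genes higher), 0.20 for ribosomal proteins (30 of 38), 0.21 for oxidative phosphorylation (15 of 20), 0.56 for hypoxia (16 of 23) and 0.31 for epithelial junctions (10 of 16). They were 0.31 for sterol synthesis (9 of 16), 0.26 for fatty acid synthesis (6 of 11), 0.28 for unfolded protein stress (11 of 16) and 1.39 for red blood cells (8 of 8).

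Between carcinoma and normal gland edgeR called 1 gene, Cfd, where 1626 genes had an unadjusted p under 0.05. The DESeq2 Wald test called 177 genes, 119 higher and 58 lower, without Cfd (log2 -11.58), and limma voom called 316, 8 higher and 308 lower. The count was 0 with the number of detected genes as a covariate (Cfd at -9.07) and without normal 18 (-9.93). It was 2 with DESeq2 size factors, without a filter, with a stricter filter or without the 3 libraries of fewest genes, and 7 with these stages alone. Genes of smallest p, as values only, were the water channel gene Aqp5 (945 ± 745 against 175 ± 17.4 CPM), Kcnn4 (1103 ± 637 against 263 ± 115 CPM), Dtymk, Ube2c and Tmem147, higher in carcinoma, and Wfdc12, Olfr787 and Satl1, lower. Normal means with and without normal 28 were 44.5 and 5.47 CPM for Olfr787 and 41.4 and 17.8 for Satl1, and with and without normal 18 they were 223 and 119 for Cfd and 84.6 and 36.1 for Car3. Of 18 lists, 5 held with an estimated correlation: adipocyte (adjusted p = 0.00258), fibroblast (0.0110), epithelial-mesenchymal transition (0.0166), macrophage (0.0314) and basal (0.0489). Adjusted over the list alone, 5 adipocyte, 2 neutrophil and 1 macrophage genes were lower, and 2 epithelial junction, 2 hypoxia and 1 gene each of the G2 and M phase, fatty acid and lung epithelium lists were higher. Regions share animals, and the normal libraries had the most detected genes on average. The macrophage call was lost without normal 18 (adjusted p = 0.210), the T, NK and B cell call without normal 18 (0.190) or 28 (0.0522), the neutrophil call without normal 18 (0.147) or 30 (0.0534) and the hypoxia call without normal 30 (0.0562). The red blood cell call was lost without normal 18 (0.284) or 28 (0.108) and carcinoma 37 (0.0585), 54 (0.0767), 08 (0.0671) or 55 (0.105).

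**Figure D3:**
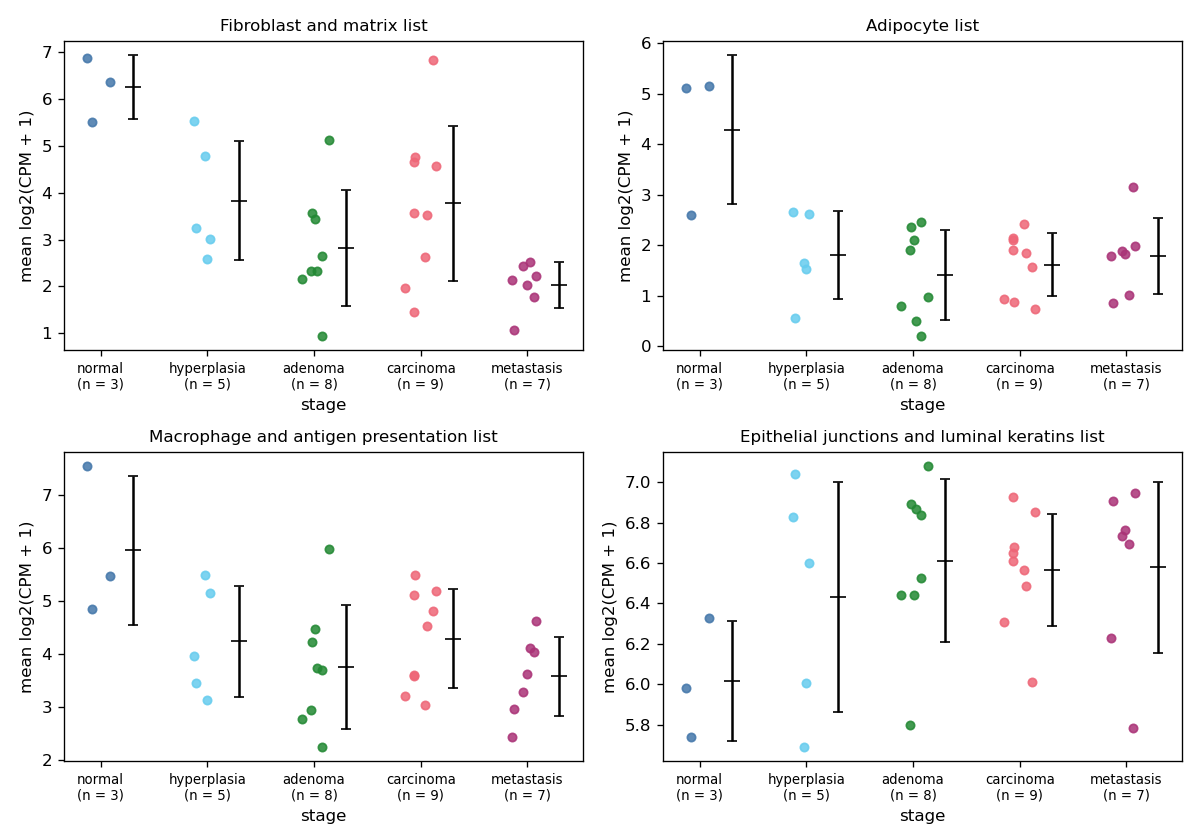
Mean log2(CPM + 1) of the fibroblast, adipocyte, macrophage and epithelial lists in each library by stage, with the mean and SD of each stage. The fibroblast score averaged 6.25 in normal gland and 2.03 in metastasis, and the epithelial score stayed between means of 6.02 and 6.61.

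The median log2 difference of all tested genes was 0 for hyperplasia over normal gland, 0.06 for adenoma over hyperplasia, 0.02 for carcinoma over adenoma, -0.01 for metastasis over carcinoma and 0.10 for carcinoma over normal gland. Scaling by DESeq2 size factors in place of TMM shifted single differences against normal gland by a median of -0.39 for hyperplasia and -0.42 for carcinoma, and camera's list tests are made relative to all other genes. Among all 50 list calls, the interferon list of metastasis over carcinoma was the 1 whose median and mean had the other sign than its test. The self-contained test fry, which asks whether a list's genes move on balance one way, passed for 6, 0, 0, 4 and 7 of the called lists in the order of comparisons above. The skeletal muscle and hormone-sensing luminal lists were called in no comparison, with camera adjusted p of at least 0.177 and 0.139.

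Tumour core and border were compared to ask whether position within a tumour goes with expression. In carcinoma, Lcn2, a secreted iron-binding protein, stood at 3049 ± 1265 CPM in the core and 6387 ± 2429 CPM at the border (SD, n = 6 and 3). Stc1, a secreted hormone of calcium balance, stood at 24.6 ± 35 against 0.0580 ± 0.100 CPM, and Usp15, which removes ubiquitin, at 73.9 ± 47.6 against 4.14 ± 3.06 CPM. Nup43, Clk1 and Fundc2 were among those higher in the core and Dnaaf2, Pag1, Mir6236 and Epb41l4a among those lower. Border means with and without carcinoma 39 were 378 and 37.7 CPM for Dnaaf2, 274 and 10.9 for Pag1 and 2857 and 136 for Mir6236, against 27, 4.78 and 305 in the core. Core means with and without carcinoma 06 were 24.6 and 13.4 for Stc1 and 28.2 and 16.9 for Nup43. None passed: edgeR called 0 genes, with 1276 of 22676 at an unadjusted p under 0.05 against a median of 1468 in other splits of the same libraries, and the DESeq2 Wald test called 314, 263 higher and 51 lower. The count was 1 without carcinoma 06 and 1 without carcinoma 37, and regions share animals.

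In adenoma, Cpe, an enzyme that trims peptide hormones, stood at 148 ± 44.5 CPM in the core and 1.81 ± 2.59 CPM at the border (SD, n = 3 and 3, edgeR adjusted p = 0.103). The matrix protein Mgp stood at 18.2 ± 18.6 against 209 ± 143 CPM. Mfge8, a milk fat globule protein, stood at 50.5 ± 43.0 in the core against 695 ± 510 CPM at the border. Nek6, Ccn1 and Ikzf2 were among the genes higher in the core and Mbd5, Hba-a1 and Hba-a2 among those lower. Core means with and without adenoma 51 were 472 and 68.6 CPM for Nek6, 177 and 38.6 for Ccn1 and 324 and 18.1 for Ikzf2. Border means with and without adenoma 36 were 583 and 126 for Hba-a1 and 577 and 124 for Hba-a2. The edgeR fit called 0 genes, with 2143 at an unadjusted p under 0.05, and the DESeq2 Wald test called 1143, 678 higher and 465 lower. The count was 2 without a filter and 1 without adenoma 47, and regions share animals. Whether the core to border difference itself differed between carcinoma and adenoma was tested as an interaction, in which edgeR called 0 genes, with 1988 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0889.

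In metastasis, Jchain, of antibody-secreting cells, stood at 119 ± 182 CPM at the lung border and 0.537 ± 0.930 CPM in the lung centre (SD, n = 4 and 3). The actin-binding gene Afap1 stood at 84.5 ± 64.4 against 8.85 ± 3.04 CPM and the focal adhesion gene Tes at 11.4 ± 11.3 against 154 ± 140 CPM. Lrrc4c, Antxr2 and Tmprss13 were among the genes higher at the border and Zfp937, Cdk13 and Rag2 among those lower. Centre means with and without metastasis 42 were 342 and 12.7 CPM for Zfp937, 325 and 31.7 for Cdk13, 80.7 and 23.0 for Rag2 and 154 and 79.5 for Tes. Border means were 119 and 28.7 for Jchain and 47.7 and 10.6 for Antxr2 with and without metastasis 56. They were 33.9 and 10.0 for Lrrc4c with and without metastasis 40, and 74.7 and 41.6 for Tmprss13 with and without metastasis 57. By edgeR 0 genes were called, with 1975 at an unadjusted p under 0.05 and a smallest adjusted p of 0.459, and the DESeq2 Wald test called 744, 603 higher and 141 lower. The median log2 of all genes was 0.30, the count was 1 without a filter, and regions share animals.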

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

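Tests of carry-over, host lung tissue, lung position, a common dilution, Y-linked counts, transcript loss and X-linked expression were chosen after the result was seen. The tests of other splits, depth and detected genes were set before.

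Some libraries lay far from the others of their stage, by the gap to the nearest other library over the range of the stage. This held for 27 of 182 groups of values, where chance gives about 1 in 20 groups, or 9.1. That rate does not apply to the 10 of the 27 that were levels of surfactant genes or Cfd, since in 9 of these the nearest other library was at 0, and 5 were of proliferation, S phase and G2 and M phase scores, which share genes. Of the 27, 7 were in adenoma 51 and 6 in hyperplasia 22. The proliferation score was low in hyperplasia 22 (1.68) and adenoma 51 (2.23), as were the G2 and M phase scores (1.89 and 2.50) and the S phase score of adenoma 51 (1.86). Adenoma 51 was also low in the epithelial-mesenchymal transition score (0.66), the unfolded protein score (4.70) and Mki67 (4.58 in log2(CPM + 1)), and hyperplasia 22 was low in sterol synthesis (1.58) and Ccnb1 (0) and high in immediate early genes (7.48). The milk score (9.19) and Csn2 (12.94) were high in hyperplasia 46, the neutrophil score in metastasis 02 (7.01) and the hypoxia score in carcinoma 37 (6.60). Krt18 was low in adenoma 47 (8.05) and Cdh1 in carcinoma 53 (5.66). Among genes at or near 0 in the other libraries of the stage, Sftpc was high in hyperplasia 22 (0.16), adenoma 36 (0.51) and carcinoma 39 (0.71), Sftpa1 in hyperplasia 33 (2.43) and carcinoma 39 (1.04), Sftpb in hyperplasia 44 (0.57) and adenoma 51 (0.36), and Cfd in hyperplasia 21 (3.38), carcinoma 07 (0.93) and metastasis 58 (0.27).

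Surfactant genes were high in 7 of 7 metastases. Reads carried over between libraries are argued against for Sftpc, since the lowest metastasis held 387 times the level of the highest of the other 25 libraries. By the same measure they stay open for Sftpb, at 31.3 times, and for Sftpa1, at 2.66 times. The Sftpa1 ratio rests on hyperplasia 33 (4.40 CPM), where Sftpc, the most abundant of these genes in metastases, was at 0. Lung tissue of the host inside the captured regions may be a source: Ager, of alveolar type 1 cells, exceeded the highest other library (8.35 CPM) in 6 of 7 metastases, which ran from 1.19 to 74.8 CPM. Whether regions at the lung border held more of it stays open, with mean log2 Sftpc of 9.75 at the border and 10.15 in the centre (exact permutation p = 0.743, 35 splits). Expression by tumour cells grown in the lung, the site the design names, was not tested.

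Connective tissue, fat and immune lists were lower in carcinoma than in normal gland (8 lists, 6 of them of other cell types than epithelium). A single dilution of all other cells as the whole cause stays open. The 11 adipocyte genes had a median log2 of -4.00 and the 72 genes of the other lists -1.58 (permutation p = 0.00042, with genes not independent). This test cannot decide, since the adipocyte list was set apart after its fall was seen. Adipocyte genes near 0 in carcinoma, such as Cfd (mean 0.100 CPM), also have uncertain differences. A linear effect of detected genes and total depth as the whole cause are argued against at the preset correlation only. There 8 of 8 lists were still called with detected genes as a covariate and 8 of 8 with every library thinned to the lowest total. At that correlation other splits called a median of 7 lists, and the endothelial, T, NK and B cell and neutrophil calls did not hold with an estimated correlation. Thinning evens out reads and not captured molecules, so a difference in captured molecules stays open. A change in the share of single cell types with stage stays open and untested, as does the pooling of normal 28 and 30. Normal 18, which the labels place in the tumour core and do not call a pool, had fibroblast, macrophage and adipocyte scores of 6.87, 7.54 and 5.12. The pools had 5.52 and 6.37, 4.85 and 5.47, and 2.59 and 5.16. Site and pooling cannot be told apart in these libraries.

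Xist, the RNA that silences an X chromosome in female cells, stood at 8.65 CPM in metastasis 42 and 9.66 CPM in metastasis 58, against 379 to 4261 CPM in the other 30 libraries. Tissue of a male animal is argued against, with 1 count over 4 Y-linked genes in these libraries. Random loss of abundant transcripts is argued against, since 1.92% of 104 genes of 500 to 2500 CPM were under a twentieth of their median in metastasis 58 and 1.92% in metastasis 42. Transcription from both X chromosomes stays open: X-linked genes deviated by 0.0228 more than autosomal genes in metastasis 58 and by 0.29 less in metastasis 42 (-0.29), both within -0.53 to 0.28 of the other libraries. No biological explanation is given by the design.

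Other splits of the same libraries were fitted to ask whether chance can be excluded for each count. The splits treat regions as independent, though regions share animals. On that footing, a share of splits under 0.05 reached the number of genes in metastasis against carcinoma (3, reached by 4 of 100 splits, highest other 13). The same held for the lists in hyperplasia against normal (16, 1 of 56 splits, highest other 14) and carcinoma against normal (18, 2 of 98, highest other 20). These shares are not adjusted for the many counts tested, so chance is less likely there but is not excluded. A count of 0 genes is reached by every split, so the splits decide nothing for hyperplasia against normal (56 of 56, highest other 1), adenoma against hyperplasia (100 of 100, highest other 10), carcinoma against adenoma (100 of 100, highest other 1), carcinoma core against border (25 of 25, highest other 2) and lung border against centre (25 of 25, highest other 6). Chance cannot be excluded for the genes in carcinoma against normal (1, 5 of 100, highest other 3), nor for the lists in adenoma against hyperplasia (1, 94 of 100, highest other 13), carcinoma against adenoma (3, 86 of 99, highest other 13) and metastasis against carcinoma (12, 8 of 99, highest other 15). Other splits called a median of 6, 5, 6, 6 and 7 lists for the stages in the order of the report. A camera call at the preset correlation is thus not by itself evidence of a difference between stages. At an unadjusted p under 0.05 the counts were reached by 7 of 56 splits (2472, highest other 3928), 84 of 100 (2947, 5418), 12 of 100 (2502, 2892), 13 of 100 (2164, 3001) and 9 of 100 (1626, 2665) for the stages in the order of the report, by 23 of 25 (1276, 2366) for carcinoma positions and by 11 of 25 (1975, 2560) for lung positions, so chance cannot be excluded for these. The 10 splits of the adenoma positions are too few for a share under 0.05: 10 gave as many genes as called (0, highest other 2) and 7 as many at an unadjusted p under 0.05 (2143, highest other 2665). Some splits called several times the real count, such as 13 genes against 3, as a structure of the samples other than stage may give, and what drove them was not tested.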

How the results depend on the processing

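The alternatives without the gene ID of highest share and without the 3 libraries of fewest detected genes were chosen after the result was seen, and the others were set before. No called gene changed its sign and no called list its camera direction. The median log2 of the called S phase list in carcinoma against normal did change sign, from 0.48 to -0.09 with DESeq2 size factors. Of the pairs of a named gene and a comparison that were not called, 12 had the other sign in at least 1 alternative, 14 values in all, among them Mir6236 in carcinoma positions, at -3.23, and 1.23 without carcinoma 39. Of the named genes, 5335 values were the same, 263 moved, 125 were stronger and 3 weaker, and of the single list calls 737 were the same and 113 weaker. For a gene called in neither fit, same means a log2 shift within its reported SE, which is wide at this dispersion. Stronger means called only in the alternative, by any tool, and weaker means no longer called. The same values thus do not show stability: Jchain in carcinoma against normal counted as the same at -1.62, and 0.03 without normal 18. The DESeq2 Wald test called 489 genes for hyperplasia against normal, 609 for adenoma against hyperplasia, 265 for carcinoma against adenoma, 186 for metastasis against carcinoma, and 177 for carcinoma against normal, where simulated data without change gave it 72 to 442 calls. It called 314 for carcinoma core against border, 1143 for adenoma core against border and 744 for lung border against centre, which were not simulated. limma voom called 105, 2, 7, 19 and 316 for the stages in the same order. With the compared stages alone edgeR called 1 for hyperplasia against normal and 7 for carcinoma against normal, where fewer libraries and genes were fitted. With detected genes as a covariate it called 168 for carcinoma against adenoma and 0 for carcinoma against normal. Without a filter it called 5 for metastasis against carcinoma, 2 for carcinoma against normal, 2 for adenoma positions and 1 for lung positions. For carcinoma against normal it called 2 with DESeq2 size factors, 2 with a stricter filter and 2 without the 3 libraries. With an estimated correlation the lists called were 3, 0, 0, 4 and 5. Lists in adenoma against hyperplasia numbered 2 without the 3 libraries, and lists in carcinoma against adenoma 5 with DESeq2 size factors and 5 with the covariate. Leaving out each library in turn gave 0 to 1 genes for carcinoma against adenoma, for carcinoma against normal, for carcinoma positions and for adenoma positions, 0 to 6 lists for adenoma against hyperplasia and 2 to 7 for carcinoma against adenoma. The level of proliferation between stages gave permutation p = 0.0447 without the 3 libraries, against 0.327 to 0.805 with each library left out and 0.210 to 0.547 for its spread. Where no reason is named, the cause was not tested. At the depths of these libraries, 2688611 counts in the smallest, and a dispersion of 2.64, 2 to 30% of simulated 4-fold changes in genes of 20 CPM or more were recovered. The part due to depth was not tested. The range of the number in the sample titles, whose meaning is not given, moved no count beyond 1.5 times when used as a block.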

Other observations

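The spread of the lists other than proliferation was compared with random lists by the plan set before, and the values without the 3 libraries with fewer than 11000 detected genes were chosen after the result was seen. Red blood cell genes varied most within stages, with a pooled SD of 2.97 against a median of 0.43 for random lists of like expression, and their score ran from 0 to 9.78 in adenoma and from 4.69 to 11.95 in metastasis. Globin genes are near-identical copies, so this list holds few independent genes. Interferon response genes came next (SD 1.46 against 0.39), with scores from 1.31 to 6.22 in adenoma and from 2.45 to 6.97 in metastasis. Fibroblast and matrix genes (SD 1.24 against 0.45) ran from 1.45 to 6.84 in carcinoma, macrophage genes (1.02 against 0.42) from 2.24 to 5.98 in adenoma, and milk genes (0.88 against 0.35) from 5.42 to 9.19 in hyperplasia. For each of these, permutation p = 0.0001, the smallest the random lists can give, with adjusted p = 0.00024. As for proliferation, the random lists were not matched on co-regulation, so genes that move together pass more readily.

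Endothelial genes (SD 0.60 against 0.66, permutation p = 0.741), lung epithelium genes (0.40 against 0.47, p = 0.848 by the same permutation) and epithelial junction genes (0.40 against 0.37, permutation p = 0.301) were not shown to vary within stages beyond random lists. Without the 3 libraries the pooled SD was 3.03 for red blood cell, 1.38 for interferon, 1.17 for fibroblast, 0.90 for macrophage and 0.83 for milk genes, against 0.37, 0.29, 0.38, 0.33 and 0.29 for random lists, and these still passed. That of the proliferation score went from 0.81 to 0.48, against 0.19. Csn2, a casein, stood at 3158 CPM in metastasis 42 and 1565 CPM in metastasis 58, the libraries with Xist under 10 CPM, and regions share animals.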
